A study of Mus musculus with 11 samples.

How the data were processed

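RNA of 7 ovarian tumours and 4 normal ovaries of mice was measured on Affymetrix whole-genome mouse arrays, with 1 array per sample and biotin-labelled target made from total RNA, per the labels' protocols. The deposited values are on a log10 scale. Raised back to linear values they are whole numbers to within 0.001, none under 50, and 77 values equal 50. The median of every array is 226, and the sorted values of any pair of arrays lie within 0.163 of each other on the log2 scale, so their distributions are alike but not identical. The algorithm and any added constant are not given in the sources used here. The 27 control probe sets for bacterial transcripts that were not targeted read a median of 103 and at most 136, so a constant near 100 may lie under every value, and folds of dim genes are then understated.

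The log10 values were multiplied to log2 and used without further normalization, since the array medians differed by less than 0.1. The 64 control probe sets were left out of the tests. Of the 45037 others, 34945 name 1 gene in the platform annotation, 932 several and 9160 none. Genes were named from probe sets that name 1 gene, and 34754 of those symbols' probe sets matched the gene table of assembly GRCm38.p6, which was used for names alone. Each gene was represented by its probe set with the highest mean over the 11 arrays, so its fold can differ on its other probe sets. Of the genes, 678 have probe sets that passed in opposite directions.

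Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A group whose arrays all read at or below the highest untargeted control has only a bound, and its fold is given as at least the other group's mean over that control level. After the data were seen this was extended to groups whose mean lies at or below the mean control level, with each array raised to at least its own. Of the passing genes, 302 had all normal ovaries and 214 had all tumours at that level. The 27 gene lists, with 487 members of which 441 had a probe set, were tested with camera at a preset correlation of 0.01 and again with an estimated one. Exact permutation tests used all 330 splits, with a smallest p of 0.00303. There are 3 replicate numbers that occur in both groups, and they entered only as alternatives, with statmod 1.5.0 for the random block.

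The groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes are the 12 with the largest rise and the 12 with the largest fall among passing genes whose groups do not overlap, up to 3 passing members per list in the list's main direction and 1 in the other, and Apc and Pten. Alternatives covered quantile normalization, equal medians, a filter on the dimmest 40% of probe sets, variance models, array weights, the replicate number, RNA quality, the choice of probe set, the list test and leaving out each array. Added after the data were seen were removal of an offset of 100 with a pseudocount of 16, the actin ratio as a covariate, leaving out the 3 arrays with the highest actin ratio, an own spread per group, the exact test of list scores, and 6 further gene lists. The log10 values needed no pseudocount, so the alternatives for a linear table did not apply.

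The fit was tested on simulated data with 200 changed probe sets among 45037. For the comparison over all 11 arrays it recovered 58% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. Of its calls, 19.8% were false where each group kept its own spread per probe set, and 3.89% where both groups had equal spread. The fit of 3 pairs recovered 0%, 2%, 64% and 90%, with 2.5% false calls. In the real comparison 19727 probe sets passed, which makes the adjusted threshold less strict than with 200 changed. The recovered and false shares of the simulation therefore do not carry over to the real calls. The list test found 2 of 2 shifted lists and 0 of 25 others. The simulated probe sets varied independently, while the estimated correlation within the real lists reached 0.822. The 0 of 25 therefore does not give the rate of false lists in these data. Pten was not analysed here. Figures were drawn with matplotlib 3.10.9.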

Results

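Gene expression was measured in ovarian tumours of mice and in normal mouse ovary, with 1 array per sample. The series title names an endometrioid ovarian adenocarcinoma model made by conditional inactivation of Apc and Pten, and the strain labels give both genes as flanked by loxP sites, which Cre recombinase uses to delete what lies between them. Apc restrains beta-catenin in the Wnt pathway, and Pten restrains PI3K signalling. There were 7 ovarian tumours and 4 normal ovaries, 11 arrays in all, named here by their labels. Each array gave values for 45037 probe sets once the control probe sets were left out, and 18193 genes were represented by 1 probe set each. The median signal was 226 on every array, and between 68.6% and 81.4% of probe sets per array lay above all 27 control probe sets for bacterial transcripts. The number of arrays limits the precision. The labels call the samples individual, and p-values measure the spread between them.

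The targeted gene Apc was higher in the tumours on 4 of its 4 probe sets. The probe set with the highest mean signal read 11.34 ± 0.19 in tumours (log2, SD, n = 7) against 10.31 ± 0.13 in normal ovaries (SD, n = 4), a 2.04-fold difference with a limma adjusted p of 7.19e-06. The folds of the other 3 probe sets were 2.04, 3.04 and at least 1.22, the last with all normal ovaries at the level of the untargeted controls. The labels do not say which part of the gene is deleted, and a probe set outside that part does not check the deletion. Pten was not analysed here, since no probe set is listed for it in the annotation used.

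**Figure D1:**
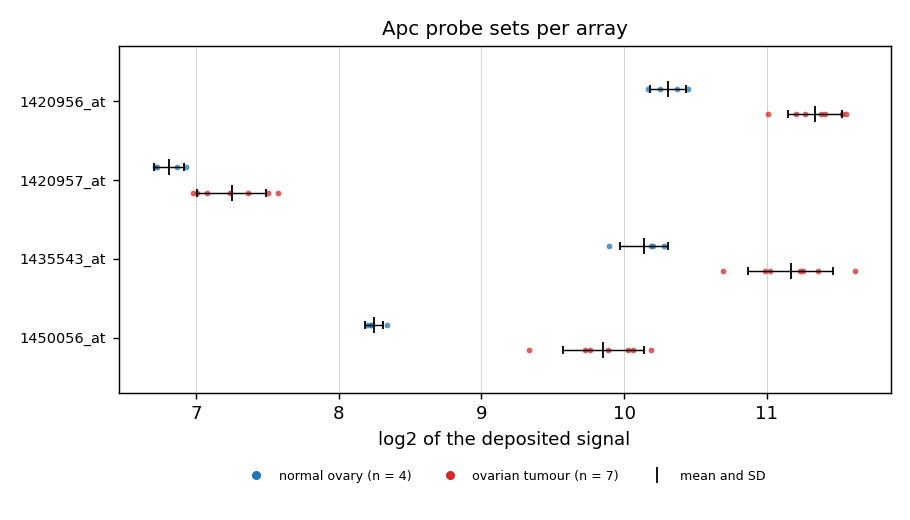
Log2 signal (x axis) of the 4 Apc probe sets (y axis) on each array, with normal ovaries in blue, tumours in red, and black bars for the mean and SD. The tumour means lie above the normal means on each of the 4 probe sets, with 11.34 against 10.31 for the probe set of highest mean signal.

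The comparison of tumours with normal ovaries asked which transcripts differ once the tumours have formed. Tumours carried high levels of Ptn, which encodes the growth factor pleiotrophin, of Slc38a4, an amino acid transporter, and of the keratin genes Krt4 and Krt23. Ptn was 52.0-fold higher, at 14.23 ± 0.19 in tumours (log2, SD, n = 7) against 8.53 ± 1.10 in normal ovaries (SD, n = 4), with a limma adjusted p of 1.15e-07. Upb1 was 49.5-fold higher, Slc38a4 45.2-fold, Krt4 42.4-fold, Avil 41.9-fold and Chodl 40.4-fold. Tnfrsf11b, which encodes osteoprotegerin, was at least 31.8-fold higher, followed by Krt23 at 36.9-fold, Sbspon at 36.5-fold, Clic6 at 36.2-fold and Sp5 at 34.7-fold. Lypd2 read the lowest value of the table in all 4 normal ovaries and was at least 15.7-fold higher in tumours. Normal_Ovary_1050N held higher signals of many of these genes than the other normal ovaries: Ptn read 1130 there against 208 to 316 in the other 3, and 15658 to 22148 in the tumours. Without that array Slc38a4 was 69.8-fold higher. Many of these genes read near the untargeted controls in normal ovaries, so the size and order of their folds depend on the offset under the values. With an offset of 100 removed, 10 of the 12 folds moved by more than 1.5 times.

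The largest falls included genes of steroid synthesis and of granulosa cells. Cyp11a1, whose product makes pregnenolone from cholesterol, was 136-fold lower, at 7.28 ± 0.84 in tumours (log2, SD, n = 7) against 14.37 ± 0.28 in normal ovaries (SD, n = 4), with a limma adjusted p of 3.49e-08. Hsd3b1 was 84.1-fold lower, and Nr5a2, which encodes a nuclear receptor of granulosa cells, 82.9-fold. Inha, which encodes the inhibin alpha subunit, was 79.1-fold lower, Hao2 67.3-fold, Hsd17b1 59.6-fold and Acsbg1 59.3-fold. Mgarp was 49.1-fold lower, Slc26a7 47.2-fold, Cyp17a1 42.5-fold, Cnmd at least 37.1-fold and Ephx2 40.8-fold. Without Normal_Ovary_1026N Cyp17a1 was 67.2-fold lower. With the offset of 100 removed, 9 of the 12 folds moved by more than 1.5 times, so their size and order depend on it too. The folds are also those of 1 probe set per gene, and 2 of the 3 probe sets of Cyp11a1 passed downward. Over the alternatives, the mean of all probe sets included, the log2 difference of Cyp11a1 ran from -8.48 to -2.55. That of Nr5a2 ran from -7.61 to -4.24. Ovarian_Tumor_1030T held more of several of these transcripts than the other tumours, with Cyp11a1 at 538 against 85 to 154.

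**Figure D2:**
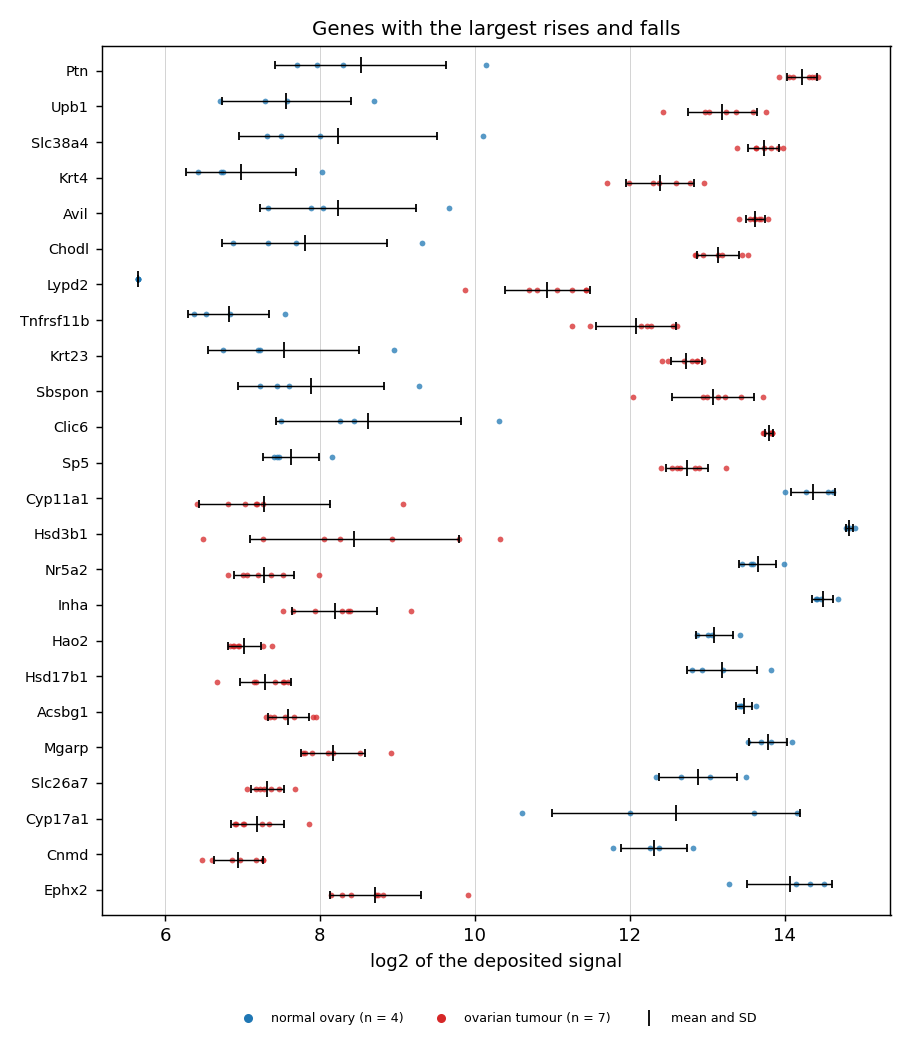
Log2 signal (x axis) of the 12 genes with the largest rises and the 12 with the largest falls (y axis), with normal ovaries in blue, tumours in red, and black bars for the mean and SD. The groups do not overlap for any of the 24 genes, which is part of the rule that chose them, and the 4 normal ovaries coincide at the lowest value for Lypd2.

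Over all genes, 3934 were higher and 4726 lower in tumours at a limma adjusted p under 0.05, which is 21.6% and 26.0% of the genes. With at least a 2-fold difference, 1305 were higher and 1373 lower. Every tumour lay above every normal ovary for 2858 genes and below for 3454, where chance separates 0.606% of genes in either direction. By probe set, 9316 were higher and 10411 lower. The 3' to 5' signal ratio of the Gapdh control probe sets, a sign of RNA integrity, also differed between the groups, at -0.23 ± 0.13 in tumours (log2, SD, n = 7) and 0.13 ± 0.15 in normal ovaries (SD, n = 4; exact permutation p = 0.00606, two-sided). With that ratio as a covariate, 2350 genes were higher and 2616 lower. Of 111 genes chosen by the rule for named genes, 22 no longer passed with it: Aldoc, Hsd17b7, Fdft1, Dhcr7, E2f1, Ccne2, Bub1b, Rsph1, Dnali1, S100a4, Thy1, Cd68, Cd22, Mzb1, H2-Ob, Egln3, Ramp3, Hba-a2, Klf1, Acta1, Vil1 and Fabp2. For 6 of the 22 the log2 difference was at least as large with the covariate, and the median SE rose from 0.212 to 0.370.

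Target genes of Wnt and beta-catenin signalling rose together. Of 28 measured members, 23 were higher and 0 lower, and 25 were higher and 1 lower when adjusted over the list alone. The mean log2 difference was 2.64 (camera adjusted p = 1.57e-14 with the preset correlation; adjusted p = 0.17 with an estimated correlation). Sp5, a transcription factor gene, was 34.7-fold higher, Notum, which encodes a secreted Wnt inhibitor, 33.5-fold, and Dkk2, another secreted Wnt modulator, 22.4-fold.

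Of the epithelial lists, 2 rose and 1 fell. Of 26 Müllerian and simple epithelial genes, 19 were higher and 3 lower, and 20 were higher and 3 lower when adjusted over the list alone, with a mean log2 difference of 1.86 (camera adjusted p = 2.11e-06 with the preset correlation; adjusted p = 0.41 with an estimated correlation). The tight junction gene Cldn7 was 11.4-fold higher, and the keratin gene Krt19 was 11.3-fold higher, with Krt18 at a log2 difference of 3.46, while the homeobox gene Emx2 was 3.58-fold lower. Of 16 squamous epithelial genes, 12 were higher and 1 lower, the same counts when adjusted over the list alone, with a mean log2 difference of 1.43 (camera adjusted p = 0.000537 with the preset correlation; adjusted p = 0.297 with an estimated correlation). Dsc3, which encodes a desmosomal cadherin, was 15.5-fold higher and Krt14 at least 4.47-fold, while the transcription factor gene Trp63 was 2.34-fold lower. Which cells of the normal ovary held the Trp63 transcript is not shown by these values. Trp63 passed on only 1 of its 4 probe sets, and its log2 difference ran from -1.99 to -0.36 over the alternatives. Of 12 genes of ovarian surface epithelium and mesothelium, 8 were lower and 2 higher, also when adjusted over the list alone, with a mean log2 difference of -0.67 (camera adjusted p = 0.0469 with the preset correlation; adjusted p = 0.582 with an estimated correlation). Bnc2 was 12.6-fold lower, Wt1 3.82-fold and Bnc1 3.40-fold, while Msln, which encodes mesothelin, was 12.6-fold higher. Members thus went both ways, and the values do not show whether those that fell came from surface epithelium or from other cells. Bnc2 passed on 2 of its 3 probe sets, and its log2 difference ran from -5.03 to -1.68 over the alternatives. This list no longer passed when any of 5 single arrays was left out, nor under 6 other alternatives, and its adjusted p ran from 0.000955 to 0.582.

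The genes of the ovary's own cell types fell. Of 25 oocyte genes, 24 were lower and 0 higher, also when adjusted over the list alone, with a mean log2 difference of -2.80 (camera adjusted p = 5.99e-17 with the preset correlation; adjusted p = 0.17 with an estimated correlation). Padi6 was 21.2-fold lower, and Ooep and Gdf9, the latter a growth factor gene of oocytes, were each 20.5-fold lower. Of 15 granulosa cell genes, 13 were lower and 0 higher, also when adjusted over the list alone, with a mean log2 difference of -2.90 (camera adjusted p = 2.59e-07 with the preset correlation; adjusted p = 0.17 with an estimated correlation). Of 14 genes of steroidogenesis and the corpus luteum, 12 were lower and 0 higher, also when adjusted over the list alone, with a mean log2 difference of -3.89 (camera adjusted p = 2.11e-06 with the preset correlation; adjusted p = 0.17 with an estimated correlation).

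Stromal and vascular genes were lower. Of 19 fibroblast and extracellular matrix genes, 13 were lower and 1 higher, also when adjusted over the list alone, with a mean log2 difference of -1.12 (camera adjusted p = 0.00201 with the preset correlation; adjusted p = 0.297 with an estimated correlation). Tagln was 7.93-fold lower, Lum 6.67-fold and Acta2 5.25-fold, while Thy1 was 1.71-fold higher. Of 16 endothelial genes, 13 were lower and 0 higher, also when adjusted over the list alone, with a mean log2 difference of -0.91 (camera adjusted p = 8.16e-05 with the preset correlation; adjusted p = 0.17 with an estimated correlation). Tek, which encodes an angiopoietin receptor, was 3.48-fold lower, Kdr, which encodes a VEGF receptor, 3.31-fold, and Egfl7 2.47-fold. Of 19 macrophage genes, 9 were higher and 1 lower, and 10 were higher and 1 lower when adjusted over the list alone, with a mean log2 difference of 0.52 (camera adjusted p = 0.0103 with the preset correlation; adjusted p = 0.582 with an estimated correlation). The complement gene C1qa was 2.54-fold higher, Cd14 2.22-fold and Aif1 2.10-fold, while Cd68 was 1.63-fold lower. The list did not pass among the 3 shared replicate numbers, with the number as a block (mean 0.33, adjusted p = 0.0859) or without it (adjusted p = 0.0652). With the block Aif1 did not pass either (adjusted p = 0.0569), and Cd68 did not pass without Normal_Ovary_1026N, Normal_Ovary_1041N or Normal_Ovary_1050N. Over all alternatives the log2 difference of Cd68 ran from -0.92 to -0.53.

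Of the metabolic lists, glycolysis rose. Of 15 glycolysis enzymes and glucose transporters, 11 were higher and 0 lower, and 12 were higher when adjusted over the list alone, with a mean log2 difference of 0.69 (camera adjusted p = 0.000646 with the preset correlation; adjusted p = 0.452 with an estimated correlation). Slc16a3, a lactate exporter gene, was 5.39-fold higher, Aldoc 2.39-fold and Hk1, a hexokinase gene, 2.29-fold. Aldoc did not pass with the Gapdh ratio as a covariate (log2 difference 1.03 ± 0.418, SE, against 1.26 ± 0.239 without it; adjusted p = 0.108). Of 16 hypoxia-induced genes, 9 were higher and 1 lower, and 10 were higher and 1 lower when adjusted over the list alone, with a mean log2 difference of 0.72 (camera adjusted p = 0.0229 with the preset correlation; adjusted p = 0.548 with an estimated correlation). Egln3 was 5.52-fold higher, P4ha2 3.77-fold and Ankrd37 3.33-fold, while P4ha1 was 1.38-fold lower on the probe set that stood for it and higher on another. The adjusted p of this list was 0.135 with the Gapdh ratio as a covariate and 0.0515 without Ovarian_Tumor_1026T. Of 18 genes activated by FOXO factors, 9 were lower and 2 higher, also when adjusted over the list alone, with a mean log2 difference of -0.58 (camera adjusted p = 0.0599 with the preset correlation; adjusted p = 0.189 with an estimated correlation). Cited2 was 8.12-fold lower, Txnip 3.46-fold and Cdkn1b, a cell cycle inhibitor gene, 3.36-fold, while the receptor gene Erbb3 was 4.63-fold higher. This list passed when any of 3 single arrays was left out and under 3 other alternatives, and its adjusted p ran from 0.0213 to 0.276.

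Cholesterol and cell cycle genes did not pass as lists. Of 19 genes of cholesterol synthesis and uptake, 10 were lower and 2 higher, also when adjusted over the list alone, with a mean log2 difference of -0.73 (camera adjusted p = 0.143). The normal ovaries differed from each other here: Hsd17b7 read 20221 in Normal_Ovary_1041N and 16239 in Normal_Ovary_1050N, against 2804 in Normal_Ovary_1026N and 2083 in Normal_Ovary_1043N, and 1226 to 1555 in the tumours. Normal_Ovary_1041N and Normal_Ovary_1050N also had the higher actin 3' to 5' ratios, 3.10 and 3.36 against 2.10 and 1.91. Ovarian_Tumor_1027T had an actin ratio of 3.19, yet its list score was -0.72, where the tumours ran from -0.81 to -0.66. A high actin ratio therefore did not come with high values of the list in that tumour. With an estimated correlation, 0.822, the list's adjusted p was 0.789. Without Normal_Ovary_1026N it was 0.00555 with the preset correlation. With the Gapdh ratio as a covariate its mean log2 difference was -0.053 (adjusted p = 0.952). The log2 difference of Hsd17b7 was then -0.69 ± 0.778 (SE) against -2.18 ± 0.533 without it, that of Fdft1 -0.94 ± 0.385 against -1.74 ± 0.271, and that of Dhcr7 -0.28 ± 0.754 against -1.59 ± 0.502. Without the 3 arrays of highest actin ratio the list's mean log2 difference was 0.060. Those arrays were Normal_Ovary_1041N, Normal_Ovary_1050N and Ovarian_Tumor_1027T. The list scores of Normal_Ovary_1041N and Normal_Ovary_1050N, 1.02 and 0.55, were the highest of the normal ovaries. Leaving them out removes the difference whatever its cause, so the 0.060 is no test of RNA quality. Of 35 cell cycle genes, 7 were higher, 2 lower and 26 did not pass, and 5 were higher and 1 lower when adjusted over the list alone, with a mean log2 difference of 0.10 (camera adjusted p = 0.334). E2f1 was 1.94-fold higher, Ccne1 1.86-fold and Ccne2 1.67-fold, while Bub1b was 1.66-fold lower. With the Gapdh ratio as a covariate the log2 difference of Ccne2 was 0.10 ± 0.278 (SE) against 0.74 ± 0.204 without it. That of E2f1 was 0.73 ± 0.241 against 0.96 ± 0.144, and that of Bub1b -0.96 ± 0.357 against -0.73 ± 0.206, and none of the 3 passed (adjusted p = 0.848, 0.0525 and 0.0796). With an estimated correlation, 0.736, the list's adjusted p was 0.863. Without Normal_Ovary_1043N it was 0.0376 with the preset correlation.

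The other lists did not pass the camera test. Of 11 oestrogen and progesterone receptor genes and targets, 4 were lower and 2 higher (adjusted p = 0.143): Greb1 was 16.7-fold lower, Esr2 at least 10.6-fold and Susd3 12.2-fold, while Ramp3 was 2.08-fold higher. The log2 difference of Susd3 ran from -4.62 to -1.95 over the alternatives. Of 16 T and NK cell genes, 2 were higher and 2 lower (adjusted p = 0.851). Zap70, a kinase gene of the T cell receptor, was 15.6-fold higher, at 11.02 ± 0.39 in tumours (log2, SD, n = 7) against 7.06 ± 0.32 in normal ovaries (SD, n = 4; limma adjusted p = 2.40e-08), and Klrd1 was 1.39-fold lower. Of 10 B and plasma cell genes, 6 were lower and 2 higher (adjusted p = 0.334), with Jchain 8.96-fold lower and Blnk 3.31-fold higher. Of 19 interferon-induced genes, 6 were lower and 4 higher (adjusted p = 0.92), with Bst2 5.07-fold lower and Oas1a, a gene with near-identical family members, 5.02-fold higher. Of 12 neutrophil genes, 2 were higher and 0 lower (adjusted p = 0.226), with S100a9 3.16-fold higher. Of 8 MHC class II genes, 2 were lower and 0 higher (adjusted p = 0.537), with H2-Oa 1.63-fold lower. Of 16 mesenchymal transition genes, 6 were higher and 5 lower (adjusted p = 0.39), with Fn1 3.73-fold higher and Cdh2 3.58-fold lower. Of 15 oviduct genes, 5 were lower and 1 higher (adjusted p = 0.24), with Ak7 3.00-fold lower and Sec14l3 2.06-fold higher. Of 8 erythroid genes, 2 were higher and 1 lower (adjusted p = 0.601), with Rhd 1.52-fold lower. Of 10 adipocyte genes, 3 were lower and 0 higher (adjusted p = 0.143), with Pparg 8.24-fold lower. Of 12 muscle genes, 4 were lower and 1 higher (adjusted p = 0.307), with Myh11 10.2-fold lower and Acta1 at least 2.34-fold higher. Of 11 pancreas and intestine genes, 4 were higher and 1 lower (adjusted p = 0.414), with Vil1 2.01-fold higher and Cpa1 at least 3.96-fold lower. Adjusted over the list alone, the counts of these 12 lists were the same except for the interferon list, with 5 higher.

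**Figure D3:**
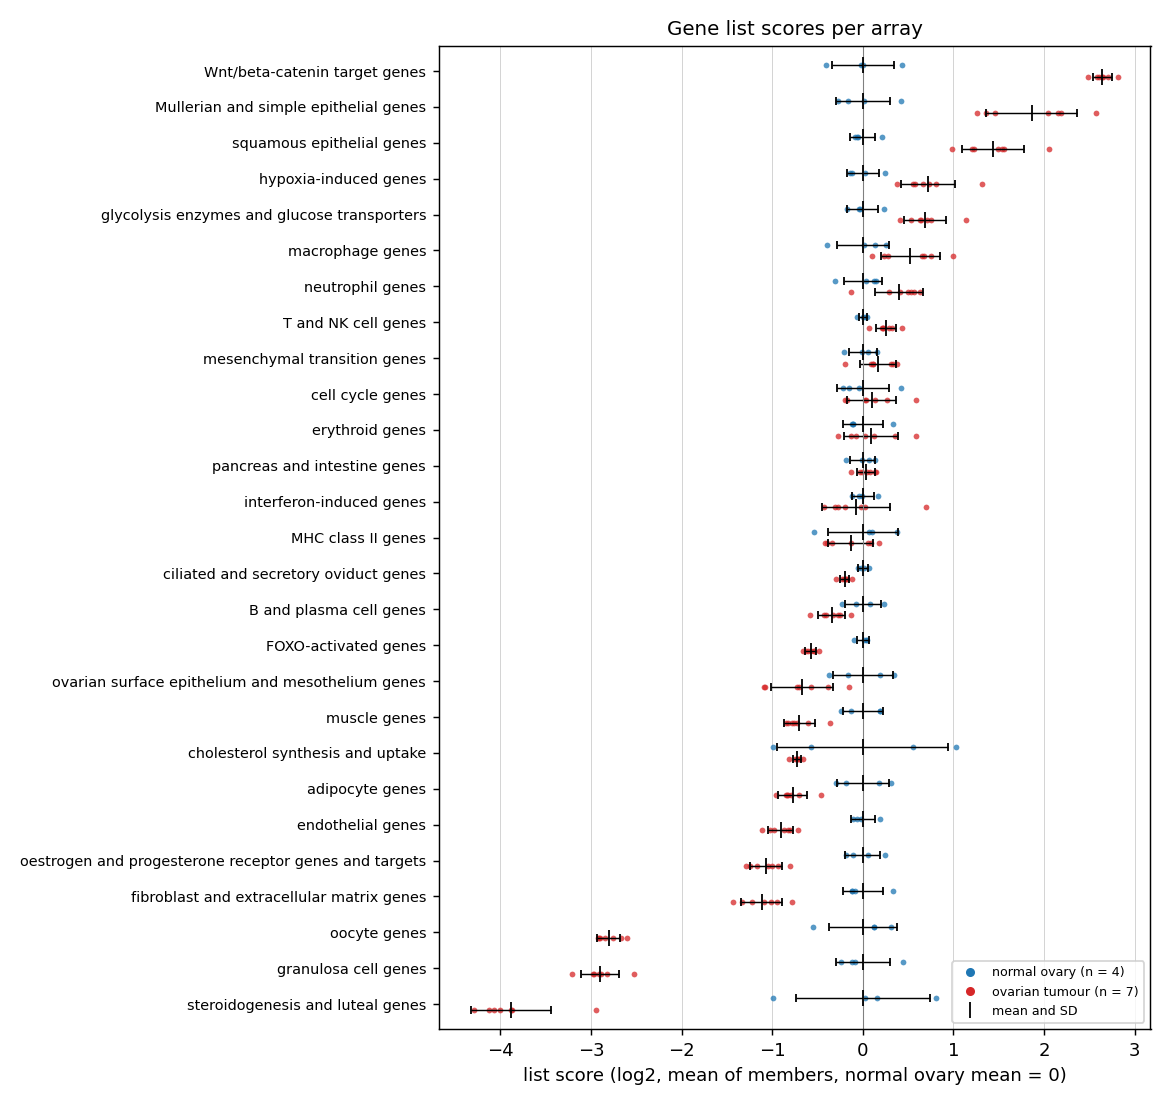
List score of each of the 27 gene lists (y axis) on each array, as the mean log2 value of the members with the mean of the normal ovaries set to 0 (x axis), with normal ovaries in blue, tumours in red, and black bars for the mean and SD. The tumours lie highest for the Wnt list, at 2.64 on average, and lowest for the steroidogenesis list, at -3.89.

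Of the 27 lists, 6 passed upward and 6 downward with the preset correlation, and 0 passed with the correlation estimated from the data, where the lowest adjusted p was 0.17. The count of 12 passing lists is not beyond that of other groupings of these arrays, since 19 of 100 splits, the real one included, gave as many. The list scores themselves, compared by an exact permutation test chosen after the data were seen, differed between the groups at an adjusted p under 0.05 for 20 of 27 lists, the 12 among them, and in 10 of those 12 the tumours lay all above or all below the normal ovaries. That test does not set a list against other genes, of which 21.6% were higher and 26.0% lower, so it does not single out the 12. The T and NK cell list, at a camera adjusted p of 0.851, also lay all above, with an exact permutation adjusted p of 0.00511. Its mean log2 difference of 0.25 rests largely on Zap70, since the other 15 genes of the list had a median of -0.044.

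Whether the tumours vary more among themselves than the normal ovaries do was tested on the same scores. The ratio of the median absolute deviations of tumours and normal ovaries passed for 0 of 27 lists by an exact permutation test (two-sided, lowest adjusted p = 0.573). At an unadjusted exact p under 0.05 there were 2: the cholesterol list, with a ratio of 0.031 and p = 0.0485, and the adipocyte list, with a ratio of 0.117 and p = 0.0455.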

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

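The tests in this part that weigh explanations were chosen after the values they weigh, or part of them, had been seen. Of 280 groups of values, 23 held a sample far from the others, or 8.21%, where chance gives about 5%.

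Among the gene list scores, Ovarian_Tumor_1030T stood above the other tumours for steroidogenesis at -2.95, and Ovarian_Tumor_1026T for interferon-induced genes at 0.69. Normal_Ovary_1050N stood above the other normal ovaries for squamous genes at 0.21, Normal_Ovary_1026N for fibroblast genes at 0.33 and Normal_Ovary_1043N for erythroid genes at 0.33. Among log2 values of single genes, Ovarian_Tumor_1030T stood above for Cyp11a1 at 9.07 and Ephx2 at 9.91, Ovarian_Tumor_1043T for Notum at 14.33, and Ovarian_Tumor_1026T for Hk1 at 12.16. Ovarian_Tumor_1040T stood below for Hsd17b7 at 10.26 and above for Emx2 at 8.69 and Lipe at 8.85. Ovarian_Tumor_1027T stood above for Fdft1 at 10.81 and below for S100a4 at 11.88, and Ovarian_Tumor_1044T above for Tagln at 11.71. Normal_Ovary_1050N stood above for Sp5 at 8.16 and Acsbg1 at 13.64, and below for Ooep at 11.49 and Cpa1 at 8.47. Normal_Ovary_1043N stood above for Emx2 at 9.67 and Normal_Ovary_1026N below for Acta1 at 6.73. Ovarian_Tumor_1027T also had the highest log2 3' to 5' ratios among tumours, at 1.67 for actin and 0.039 for Gapdh.

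Genes high in tumours were raised in Normal_Ovary_1050N. Over 52 genes with tumour means at least 4000 above the other normal ovaries, which read at most 500, its excess was a median of 3.62% of the tumour level and above 0 for 52 of 52. The medians for Normal_Ovary_1026N, Normal_Ovary_1041N and Normal_Ovary_1043N, each set against the normal ovaries other than itself and Normal_Ovary_1050N, were 0.201%, 0.332% and -0.519%; a first version that kept Normal_Ovary_1050N among the references pushed these below 0 and was replaced. RNA quality by the actin ratio is argued against, since Normal_Ovary_1041N has a similar ratio and 0.0917 times the share of Normal_Ovary_1050N. A share of tumour tissue or RNA in the sample remains a candidate explanation, but it would give every gene about the same share, and the 75th percentile was 2.03 ± 0.271 (bootstrap SE) times the 25th, which misses the bound of 2 set for it by less than its error, so the test leaves this open. That error was added after the first result, which had counted 2.03 as past the bound and so against a share of tumour tissue. The shares had medians of 4.83% in the brighter and 2.93% in the dimmer genes. No biological explanation was tested.

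Apc was higher in tumours although it is the gene to be inactivated. A single probe set that binds another transcript is argued against by 4 probe sets passing upward. With the offset of 100 removed the log2 difference was 1.08. An added constant shrinks log2 differences, so its removal could only enlarge this one, and the 1.08 was no test of the offset. With the Gapdh ratio as a covariate the log2 difference was 0.81 ± 0.169 (SE), so that measure of RNA quality does not account for the whole difference. A difference in cell types between tumour and ovary, and transcript left from a recombined allele, stay open and were not tested.

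Zap70 was higher in tumours, at a mean linear signal of 2139 against 136. More T or NK cells may be proposed, but the other 15 genes of that list had a median log2 difference of -0.044 ± 0.0573 (bootstrap SE), and Cd3e, Cd3g and Cd3d read 204, 155 and 149 in tumours, where the highest untargeted control read 136. A single probe set that binds another transcript is argued against by 3 probe sets passing upward. The difference between tumour and ovary tissue stays open, as a hypothesis that Zap70 is made by other cells of the tumour.

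The count of passing probe sets, 19727, was not reached by any of the other splits drawn: 1 of 100 splits, the real one, gave as many. The highest of the others was 92, which argues against chance. Not all 330 splits were drawn, so the share can go no lower than 1 of 100. Splits that mix the groups also hold the tumour to normal difference as spread within groups, which lowers their counts. For the count of 12 passing lists chance cannot be excluded: 19 of 100 splits gave as many, and the highest of the others was 17. Genes of a list varying together across arrays may be 1 reason. Splits that place the normal ovaries unevenly also carry part of the tumour to normal difference, and the reasons were not told apart. The scores of single lists were tested apart from that count, over all 330 splits. In 10 of the 12 lists the tumours lay all above or all below the normal ovaries, each with an exact permutation adjusted p of 0.00511, and the other lists had 0.0318 (surface epithelium) and 0.0431 (macrophage). The test of scores sets no list against other genes, many of which differed between the groups. It therefore does not tell whether these lists stand out. The fit of 3 pairs gave 13520 probe sets and the highest other exchange 0, but 4 splits, of which 1 gave as many, are too few for a share under 0.05.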

How the results depend on the processing

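Removal of the offset, the actin covariate, the 3 arrays left out and the own spread per group were chosen after the data were seen. Of 111 named genes, 82 kept their direction and side of the threshold in all alternatives run, and of 27 lists 9 did. Named genes lost their call with an own spread per group (14: Hsd17b7, Fdft1, Dhcr7, Stard4, Bub1b, Rsph1, S100a4, Thy1, Cd68, Cd22, Mzb1, P4ha1, Vil1 and Cdx2), with the fixed block (13: Hsd17b7, Dhcr7, Bub1b, Thy1, Aif1, Cd68, S100a9, Il1b, Iigp1, P4ha1, Klf1, Vil1 and Fabp2), in the same arrays without it (10: Ccne2, the others among these 13), without the 3 arrays of highest actin ratio (8: Dhcr7, Thy1, Cd68, S100a9, Cd22, Iigp1, Ramp3 and Fabp2), with the actin covariate (4: Dhcr7, Ccne2, Cd68 and Ramp3), with the mean of all probe sets (Cdx2) and with the Gapdh covariate (22). Lists under an estimated correlation lost the call with unmoved mean log2 differences: Wnt 2.64 and oocyte -2.80, granulosa -2.90, steroidogenesis -3.89 and endothelial -0.91 at an adjusted p of 0.17; squamous 1.43 and fibroblast -1.12 at 0.297; epithelial 1.86 at 0.41; glycolysis 0.69 at 0.452; hypoxia 0.72 at 0.548; surface epithelium -0.67 and macrophage 0.52 at 0.582. With the Gapdh ratio as a covariate 4542 probe sets were higher and 5242 lower, 2350 genes higher and 2616 lower, and the hypoxia list was at 0.54 (adjusted p = 0.135); the cause was not tested. The surface epithelium list lost its call without the dimmest 40% of probe sets (-0.67, adjusted p = 0.0812), with the offset removed (-1.04, adjusted p = 0.0672), with the actin covariate (-0.62, adjusted p = 0.0593), with an own spread per group (-0.67, adjusted p = 0.0562) and without members of several lists (-0.67, adjusted p = 0.0599). The hypoxia list lost it without members of several lists (0.73, adjusted p = 0.0599). The FOXO list passed with the actin covariate (-0.58, adjusted p = 0.049) and without the 3 arrays of highest actin ratio (-0.63, adjusted p = 0.0213), where the adipocyte list also passed (-1.03, adjusted p = 0.0197). P4ha1 turned to 0.19 with the mean of all its probe sets, which include 1 that passed upward. Lists that passed on neither side changed sign: the cell cycle to -0.016 with the Gapdh covariate, -0.0088 without the 3 arrays of highest actin ratio and -0.089 in the 3 shared numbers with or without the block; erythroid to -0.37 with the Gapdh and -0.13 with the actin covariate; cholesterol to 0.060 without those 3 arrays; pancreas to -0.12 without the dimmest 40% of probe sets, -0.016 with the mean of all probe sets, and -0.030 to 0.078 leaving out each array. The cause of the other changes was not tested. Leaving out each array in turn, values ran from -0.61 to -0.56 for the FOXO list (passing without Normal_Ovary_1026N, Normal_Ovary_1041N or Ovarian_Tumor_1027T), -1.06 to -0.38 for cholesterol (passing without Normal_Ovary_1026N), 0.014 to 0.24 for the cell cycle (passing without Normal_Ovary_1043N, at 0.24), -0.80 to -0.56 for surface epithelium (lost without Normal_Ovary_1043N, Normal_Ovary_1050N, Ovarian_Tumor_1026T, Ovarian_Tumor_1027T or Ovarian_Tumor_1043T) and 0.62 to 0.80 for hypoxia (lost without Ovarian_Tumor_1026T, at 0.62). Without Normal_Ovary_1050N, 3645 genes were higher and 4361 lower. Of named genes, Dhcr7 lost its call without Normal_Ovary_1041N (-1.07) or Normal_Ovary_1050N (-1.22), Thy1 without Normal_Ovary_1041N (0.63) or Normal_Ovary_1043N (0.70), S100a9 without Normal_Ovary_1043N, Cd68 without any single normal ovary but Normal_Ovary_1043N, and Fabp2 likewise and without Ovarian_Tumor_1050T. Signal near the untargeted controls limits folds of dim genes.

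The labels do not say whether samples with the same replicate number are from 1 animal. Their deviations correlated across genes at 0.009, 0.149 and -0.0047 in the 3 pairs. With the number as a fixed block over the 3 shared numbers, 2550 genes were higher and 3362 lower, the FOXO list passed (-0.58, adjusted p = 0.0337) and the macrophage list did not (0.33, adjusted p = 0.0859), nor did it in the same arrays without the block (0.33, adjusted p = 0.0652); fewer arrays entered these fits.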

Other observations

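The tests on imprinted and on bone and enamel genes in this part were chosen after some of their values had been seen (Slc38a4 and Tnfrsf11b, and Ihh from a fixed list); all 6 lists here were drawn up after the comparison over all genes. Hox genes, which set position along the body axis, were raised in part: of 29 measured, 14 were higher and 3 lower, with a mean log2 difference of 1.33 (camera adjusted p = 3.72e-06 over the 6 lists, and adjusted p = 0.00394 with an estimated correlation). Hoxb9 rose by 4.54 on the log2 scale, Hoxb6 by 4.03, Hoxb2 by 3.90 and Hoxd11 by at least 3.25, while Hoxa5 was lower, at -0.50. Of 29 Wnt ligands and receptors, 13 were higher and 5 lower, with a mean of 0.80 (adjusted p = 0.0137; adjusted p = 0.0838 with an estimated correlation). Wnt2 rose by 4.57, Wnt10a by 4.11, Fzd10 by 3.61 and Wnt6 by 3.19, while Fzd4 was lower, at -2.20.

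Of 24 chemokine genes, 9 were higher and 3 lower (adjusted p = 0.0511), with Cxcl15 at 4.88, Cxcl5 at 3.10 or more and Cxcl12 at -3.13 on the log2 scale. Of 19 bone and enamel genes, 5 were higher and 1 lower (adjusted p = 0.157), with Dlx3 at 3.37 and Bmp7 at 3.09. Of 19 imprinted growth genes, 7 were higher and 4 lower (adjusted p = 0.425): Igf2 and Cdkn1c were at 3.31 and 3.42, and Meg3 at -4.22. Of 18 NRF2 and glutathione genes, 6 were higher and 6 lower (adjusted p = 0.65), with Gpx2 at 4.02 and Gsta2 at -3.12 or lower.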
